A study of Mus musculus with 34 samples.

How the data were processed

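RNA sequencing libraries of mouse SCLC cells and tumors were analyzed from 3 tables of gene counts. The counts of reads per gene were made and deposited by the authors, and per the labels the processing notes list bcl2fastq, STAR 2.7, FastQC 0.11.9, featureCounts, Subread 2.0 and the mouse genome build mm10 without settings. Per the labels, polyadenylated RNA was sequenced for the 96 h cultures and tumors and total RNA for the 10 d cultures. The kit named in the labels does not mark the strand, so counts of genes that overlap on opposite strands are uncertain. Counts of members of near-identical families (H2, Gbp, Tgtp, Irgm and Ifit genes) are uncertain as well. Gene symbols were those of the count tables, and coordinates came from GENCODE mouse release M21. A reference list of gene names held 99.9156, 99.888 and 99.9126% of the gene identifiers in the 96 h, 10 d and tumor tables. All columns were used, each in the group its label gives.

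Each table was analyzed alone. Genes were filtered with filterByExpr, which left 13333 of 28432 genes at 96 h, 15230 of 30351 at 10 d and 14332 of 29745 in the tumors. Counts were normalized by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. The cell line was a block at 96 h (2 residual degrees of freedom), and all 4 groups of the 10 d and the tumor tables shared a fit (6 and 14). The biological coefficients of variation were 0.169, 0.104 and 0.181. p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. For group sizes this small each SE comes from the shared fit. Where a gene had 0 counts in every library of a group, the fold change is given as a bound with 3 counts over the group in place of 0, which covers counting error only. Log2 CPM used a prior count of 2. There were 12 comparisons, including an interaction in each of the 10 d and the tumor tables.

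Before the data were examined, 26 gene lists were fixed: MHC class I, MHC class II, interferon gamma response, type I interferon response, nucleic acid sensing, neuroendocrine, Notch pathway, non-neuroendocrine and mesenchymal, LSD1 complex, proliferation, chemokines for T cells, and markers of immune, stromal and other cells that a tumor could hold. A list was tested with at least 3 measured members by camera in limma 3.58.1 with a preset correlation between genes of 0.01, again with a correlation estimated from the data, and by fry, with adjustment over the lists of a comparison. Natural killer cell and neutrophil lists had too few measured members. The mean log2 CPM of each list per tumor was compared by an exact two-sided permutation test with adjustment over 120 tests. Some genes stand in a pair of lists (Cxcl9, Cxcl10 and Cxcl11 in the interferon gamma and chemokine lists, Ccl5 in the cytotoxic and chemokine lists, Ctla4 in the CD4 and checkpoint lists). Of 12 fibroblast genes 5 were measured in the cells at 96 h and 9 at 10 d.

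Genes were named by a rule fixed with the lists. It took the 6 largest rises and 6 largest falls (3 and 3 in the other comparisons) among called genes with a mean log2 CPM of at least 2 and no overlap between groups, without predicted genes. It added the 3 members (2 in tumors) with the lowest p of several lists and, in every comparison, a fixed set of genes that included Kdm1a, H2-K1, B2m, Tap1, Cd274 and Hes1. Not every gene named by this rule is printed, and 1 that it names is not reported here. Other list members printed as examples, and the muscle, fat and receptor genes, were chosen after their values were seen.

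Alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE or library size in place of TMM, no filter, a filter at 1 CPM, a fit of only the groups compared, the replicate number as a block and each library left out in turn. Added after seeing the data were fits without vehicle tumors 1 and 2, with vehicle tumor 1 thinned to the median total of the other tumors, without the transcripts Gm26917 and Gm42418, and, for the 10 d interaction, with list members at 0 counts in some groups left out. The residuals of DMSO and DMSO with IFNg libraries of the same number correlated by 0.393, 0.119 and 0.133, all above 0.1, so these libraries were treated as pairs in an alternative. For number 3, however, another DMSO with IFNg library matched better. Other 10 d groups also had values above 0.1, such as 0.200 between BOM libraries without and with IFNg. For number 1 of the 2 groups with IFNg the value was 0.230. No library was a copy of another of its group (lowest chi-square per degree of freedom 2.55), and libraries of different groups were not checked for this.

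The pipeline was tested on simulated data at the depths and average spreads of 8 comparisons. In each, 100 genes were changed 2-fold and 100 were changed 4-fold, all with a mean log2 CPM of at least 2. edgeR found 84 and 99 of them at 96 h, with 10 false calls. In the 10 d table it found 86 and 99 for BOM (5 false calls), 90 and 100 for IFNg in DMSO (3) and 84 and 98 for BOM with IFNg (14). In tumors it found 87 and 100 for BOM against vehicle (8), 93 and 100 for anti-PD1 against vehicle (12), 86 and 100 for the combination against vehicle (6) and 83 and 99 against anti-PD1 (15). Simulated genes varied independently, with a spread set by their expression level alone and no structure among samples of a group. The simulation therefore checks the code and does not measure how many such changes would be found in the real data. Totals per library are given at the start of the report.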

Results

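Gene expression was measured by RNA sequencing in mouse small cell lung cancer (SCLC), a neuroendocrine lung tumor, in 3 experiments on bomedemstat (BOM), an inhibitor of the histone demethylase LSD1, the product of Kdm1a. In the first, the SCLC lines RP-116, RP-48 and G8545 were each cultured with BOM or the solvent DMSO for 96 h, which gave 1 library per line and treatment (n = 3 per group). In the second, the line RP-48OVA-LLO190 was cultured for 10 d with DMSO (n = 3), BOM (n = 2), DMSO with interferon gamma (IFNg) during the last 48 h (n = 3) or BOM with IFNg (n = 2). In the third, flank tumors of RP-48OVA-LLO190 in immunocompetent mice were treated for 16 d with vehicle (n = 5), BOM (n = 4), an antibody against the T cell checkpoint receptor PD-1 (anti-PD1, n = 5) or BOM plus anti-PD1 (n = 4). The libraries held 8.71 to 9.97 M counts at 96 h, 5.90 to 9.04 M at 10 d and 5.64 to 82.2 M in the tumors. Vehicle tumor 1 held the 82.2 M, and the next deepest tumor held 13.2 M. The labels do not say whether the 10 d libraries came from separate cultures, so p-values there measure the spread between these samples, which may be technical.

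The 96 h comparison asked which transcripts LSD1 inhibition changes in SCLC cells in culture. No single gene passed the test, but the lists of Notch pathway genes, whose activity opposes the neuroendocrine state of SCLC, and of mesenchymal genes had medians above 0 with BOM in each of the 3 lines. The receptor gene Notch1 (ENSMUSG00000026923.15, chromosome 2, 26457903 to 26516663, mm10) went from 3.41 to 18.7 CPM (counts scaled to the library total) in RP-116, from 29.9 to 109 in RP-48 and from 4.89 to 80.5 in G8545. On the log2 scale these differences were 2.38, 1.86 and 3.98. The Notch target Hes5 differed by 1.60, 1.87 and 3.66 log2 units and the TGF-beta receptor gene Tgfbr2 (ENSMUSG00000032440.13, chromosome 9, 116084293 to 116175360) by 2.14 in RP-48 and 2.54 in G8545, while in RP-116 it had 0 counts in DMSO and 0.704 CPM in BOM.

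Of the 15 measured Notch pathway genes none passed over all genes tested, and adjusted over the list alone 7 rose (among them Notch1, Notch2, Hes1 and Jag1) and 1 fell (Lfng, a modifier of Notch receptors). The list had a median log2 fold change of 0.22 and a mean of 0.74 and lay above the other genes (camera adjusted p = 0.00423), with an adjusted p = 0.612 with an estimated correlation. Its medians in RP-116, RP-48 and G8545 were 0.26, 0.56 and 0.78. The 14 genes of the non-neuroendocrine and mesenchymal list had a median of 0.60 (adjusted p = 0.00341, and adjusted p = 0.612 with an estimated correlation), and adjusted over the list alone Vim, Cd44 and Tgfbr2 rose. Its medians were 0.12 in RP-116, where 8 of 14 genes lay higher, 0.42 in RP-48 and 1.20 in G8545. This call ended without G8545 (adjusted p = 0.0685). The lists for the interferon gamma response (7 genes, median 0.43), nucleic acid sensing (11, 0.22) and fibroblasts (5, 0.88) each had an adjusted p of 0.0382 and the list for CD4 and regulatory T cells (3, 0.74) one of 0.0464. With an estimated correlation the adjusted p was 0.612 for these 4 lists, and none of them passed without RP-48 (adjusted p = 0.0638 to 0.584) or without G8545 (0.459 to 0.628), nor the last without RP-116 (0.183) or with scaling by library size alone (0.0521). Without the line as a block these 4 lists and the non-neuroendocrine list did not pass either (0.0737 to 0.292). The MHC class I list (16 genes, median 0.15, adjusted p = 0.377) and the neuroendocrine list (23 genes, median -0.02, adjusted p = 0.349) did not pass. The 6 measured type I interferon genes had a median of -0.01 and a mean of 0.20, and the test pointed up (adjusted p = 0.605). For 3 keratinocyte genes the median was 0.21, the mean -0.01 and the test pointed down (adjusted p = 0.605).

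The edgeR fit with the cell line as a block called 0 of 13333 genes, with 812 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0565. DESeq2 called 52 genes (51 higher, 1 lower), limma voom 3, edgeR without scaling beyond library size 2 and edgeR without the filter on low counts 310 (253 higher, 57 lower). Leaving out G8545 gave 149 calls (84 higher, 65 lower), leaving out RP-116 gave 1 and leaving out RP-48 gave 0. The lowest adjusted p belonged to the intermediate filament gene Vim (ENSMUSG00000026728.9, chromosome 2, 13573927 to 13582826), with a log2 fold change of 1.76 ± 0.17 (SE), higher in 3 of 3 lines. In RP-116, however, Vim had only 0.244 CPM in DMSO and 0.352 in BOM, so that line adds little. The fitted values were 2.74 ± 0.39 for Notch1 (adjusted p = 0.170), 2.81 ± 0.46 for Hes5, 2.52 ± 0.38 for Tgfbr2, 1.32 ± 0.25 for Jag1 and 1.26 ± 0.27 for the Notch target Hes1 (ENSMUSG00000022528.8, chromosome 16, 30064384 to 30067796). Without G8545 these 5 genes and Vim passed, with adjusted p = 3.46e-07 for Notch1 and 0.0308 for Hes1, and without RP-116 Vim passed (0.0448). Kdm1a (ENSMUSG00000036940.15, chromosome 4, 136550540 to 136602723) had a fitted change of -0.15 ± 0.11 and the MHC class I heavy chain gene H2-K1 (ENSMUSG00000061232.16, chromosome 17, 33996017 to 34000347) one of 0.17 ± 0.14, both with an adjusted p of 0.922. For B2m the change was 0.05 and for Cd274 -0.47, and neither passed.

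**Figure D1:**
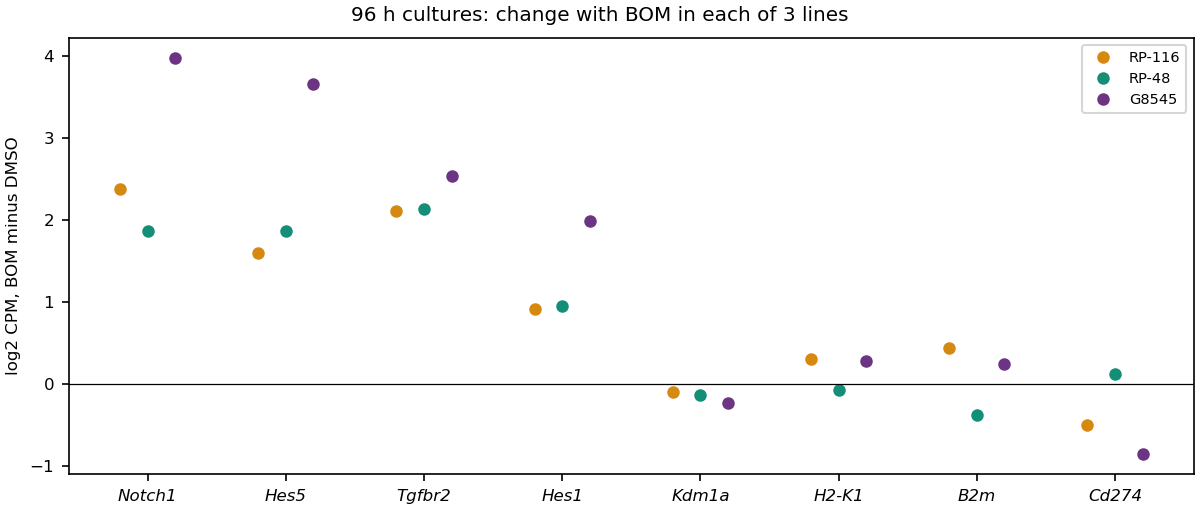
Difference in log2 CPM between BOM and DMSO after 96 h for 8 genes, with 1 point per cell line and the line at 0 marking no difference. Notch1 lay 1.86 to 3.98 log2 units higher in the 3 lines, and Tgfbr2 2.14 and 2.54 in RP-48 and G8545. Its point for RP-116, with 0 counts in DMSO, was set by the prior count.

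After 10 d in RP-48OVA-LLO190, BOM raised transcripts of Notch receptors and of mesenchymal genes. Notch1 rose from 26.8 ± 0.998 CPM (SD, n = 3) in DMSO to 256 ± 18.3 (n = 2) in BOM, a log2 fold change of 3.26 ± 0.12 (SE, adjusted p = 1.65e-11). Tgfbr2 rose by 3.18 ± 0.17, the repressor of neuronal genes Rest by 2.75 ± 0.27, the transcription factor gene Sox9 by 2.33 ± 0.15, Hes1 by 1.73 ± 0.28 and Notch2 by 1.39 ± 0.10. The largest rises included Rcan2, a regulator of calcineurin (5.45 ± 0.34, from 0.717 to 31.0 CPM), the secreted airway protein gene Bpifb1 (4.98 ± 0.28, from 11.6 to 365 CPM), the caveolar coat gene Cav1 (4.89 ± 0.49) and the potassium channel gene Kcnk9 (4.85 ± 0.23). The largest falls included the glycosyltransferase gene Mgat4c (-4.30 ± 0.43), Cib3 (-3.82), the secreted WNT antagonist Sfrp1 (-3.15) and the metalloprotease gene Adam28, which had 0 counts in both BOM libraries and was at least 47.9-fold lower (floor of 3 counts over the group). For each of these genes both BOM libraries lay on the same side of all 3 DMSO libraries. The naming rule required this of the largest rises and falls.

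Of 15 Notch pathway genes 8 rose and 1 fell (adjusted over the list alone 9 and 2), with a median log2 fold change of 0.96 (adjusted p = 6.13e-05, and adjusted p = 0.0537 with an estimated correlation). The falling gene, Lfng (-0.56), lost its call without either BOM library (0 genes fell). Of 15 non-neuroendocrine and mesenchymal genes 10 rose and 1, the cadherin gene Cdh2 (-0.53), fell (median 2.19, adjusted p = 5.47e-05, and adjusted p = 0.236 with an estimated correlation). Of the 9 fibroblast genes measured in these tumor cell cultures 7 rose, among them Col1a1 (2.77) and Pdgfrb (2.58) (median 2.50, adjusted p = 0.000164, and adjusted p = 0.236 with an estimated correlation), and 4 rose without BOM replicate 2. The 23 neuroendocrine genes went both ways (6 rose, 3 fell, median 0.03, adjusted p = 0.761), with rises in Scg2 (2.69 ± 0.14), Sez6 (1.02) and Ddc (0.90) and a fall in Foxa2 (-1.07). Of 10 LSD1 complex genes 3 fell, the corepressor gene Rcor2 (-1.40), Zmym2 (-0.33) and Kdm1a (-0.28 ± 0.08, 174 against 211 CPM), and 1 fell without either BOM library. Kdm1a was not called without BOM replicate 1 (adjusted p = 0.153), BOM replicate 2 (0.0690), DMSO replicate 2 (0.0516) or DMSO replicate 3 (0.0878), with scaling by library size alone (0.0755) or without the filter (0.0532). Of 22 proliferation genes 1 rose and 1 fell, neither of which passed without BOM replicate 1, and the 1 fall ended without DMSO replicate 2 as well.

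Some antigen presentation and interferon genes rose as well. Of 22 MHC class I genes 8 rose and 1 fell (median 0.26, adjusted p = 0.0198, and adjusted p = 0.236 with an estimated correlation), and the list's call ended without BOM replicate 1 (adjusted p = 0.0948). The peptide loading gene Tapbp rose by 0.78 ± 0.12, the peptidase gene Erap1 by 0.77 ± 0.15 and the light chain gene B2m (ENSMUSG00000060802.8, chromosome 2, 122147686 to 122153083) by 0.53 ± 0.15 (adjusted p = 0.0151). The transporter gene Tap1 (ENSMUSG00000037321.17, chromosome 17, 34187553 to 34197225) rose by 1.34 ± 0.35 from 0.725 to 1.91 CPM (adjusted p = 0.0227). H2-K1 had 34.1 against 30.1 CPM (0.17 ± 0.14, adjusted p = 0.456). The number of rising MHC class I genes was 2 without BOM replicate 1, 3 without DMSO replicate 3 and 5 without BOM replicate 2 or DMSO replicate 2, and the 1 fall ended without either BOM library or DMSO replicate 1. B2m was not called without BOM replicate 1 (adjusted p = 0.322) or DMSO replicate 3 (0.0655), and Tap1 not without BOM replicate 1 (0.0537), BOM replicate 2 (0.189), DMSO replicate 2 (0.0616) or DMSO replicate 3 (0.0828). For the interferon gamma response 4 of 17 genes rose (median 0.86, adjusted p = 0.001498, and adjusted p = 0.291 with an estimated correlation), and 2 rose without either BOM library. For the type I interferon response 4 of 19 rose (median 0.51, adjusted p = 0.0727), and 1 or 2 rose without BOM replicate 1 or 2, DMSO replicate 2 or 3 or DMSO with IFNg replicate 3. Of 12 nucleic acid sensors 4 rose, Tlr3 (2.35), Ddx58 (1.49), Ifih1 (1.30) and Mavs (0.94), and the RNA editing gene Adar fell (-0.35), a fall that ended without either BOM library. The checkpoint ligand gene Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095) stood at 0.90 ± 0.53 (adjusted p = 0.262).

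In this comparison edgeR called 3094 of 15230 genes, 1837 higher and 1257 lower, of which 863 rose and 313 fell at least 2-fold. Leaving out BOM replicate 1 gave 1858 calls and leaving out BOM replicate 2 gave 2068. Scaling by library size alone gave 2208 higher and 909 lower, so that the share of higher genes was 70.8% instead of 59.4%. One transcript, Gm26917, took 11.9 to 15.8% of all counts in the DMSO libraries and 8.36 to 9.85% in the BOM libraries.

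**Figure D2:**
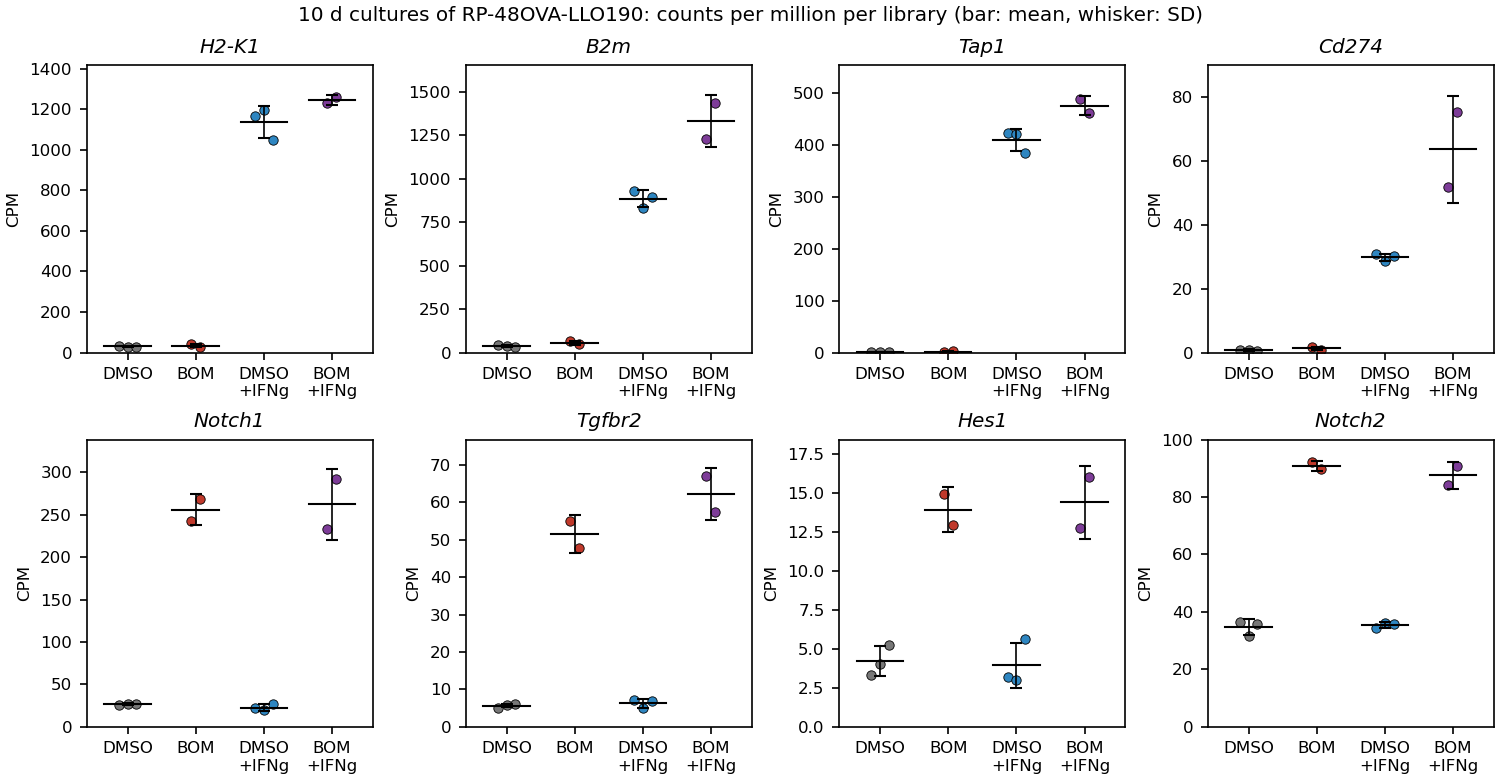
CPM of 8 genes in the 10 d cultures, with 1 point per library, bars at the group mean and whiskers of 1 SD. Notch1 stood at 256 and 262 CPM in the BOM groups without and with IFNg against 26.8 and 22.5 in the matching DMSO groups, whereas H2-K1 stood at 1244 and 1137 CPM in the groups with IFNg and at 34.1 and 30.1 without it.

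IFNg, a cytokine that induces antigen presentation, was given to ask how SCLC cells respond to it with and without BOM. In DMSO cells it raised MHC class I, MHC class II and interferon response genes. H2-K1 rose from 30.1 ± 3.58 to 1137 ± 77.4 CPM (SD, n = 3 each), a log2 fold change of 5.23 ± 0.13 (SE, adjusted p = 6.06e-15). Tap1 rose by 9.07 ± 0.15, from 0.725 to 410 CPM, B2m by 4.52 ± 0.13, and Cd274 from 0.676 to 29.9 CPM, and the transactivator gene Nlrc5 rose by 6.97 ± 0.14. The immunity-related GTPase gene Iigp1 had 0 counts in DMSO and 480.5 CPM with IFNg, at least 3015-fold higher, and the MHC class II gene H2-Ab1 was at least 142-fold higher. All 3 IFNg libraries lay above all 3 DMSO libraries for these genes, which the naming rule required of those that entered as largest rises.

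All 17 interferon gamma response genes rose (median 7.10, and 6.16 with genes at 0 set at their bound), as did 7 of 7 MHC class II genes (median 7.25, and 5.30 with bounds) and 18 of 22 MHC class I genes (median 3.41). Of 19 type I interferon genes 16 rose (adjusted over the list alone 17, median 3.48, and 10.6-fold with bounds), and 7 of 12 nucleic acid sensors rose, among them Zbp1 (5.33). With an estimated correlation the adjusted p was 0.000403 for the interferon gamma response, 0.000680 for MHC class II, 0.000102 for MHC class I, 0.000101 for type I interferon and 0.00292 for nucleic acid sensing. H2-Q7, Gbp10 and Tgtp2 were at least 150-fold, 268-fold and 173-fold higher, but these families have near-identical members and the values of single members are uncertain. Outside these lists the Notch ligand gene Jag1 fell (-0.71 ± 0.13) and the granin gene Chgb rose (0.62 ± 0.12, not called without DMSO replicate 2, adjusted p = 0.0560). The granin gene Chga stood at 0.45 ± 0.13 (adjusted p = 0.0874, and 0.000421 with the replicate number as a block) and Cd44 at 0.83 (0.0700, and 0.0106 with the block). Of 9 fibroblast genes none was called (median -0.45, adjusted p = 0.0748, and 0.0163 with the block). Notch1 (-0.25), Hes1 (-0.09) and Kdm1a (0.16) did not pass. The fit called 345 genes, 297 higher and 48 lower, and of these 186 rose and 4 fell at least 2-fold. Without the filter on low counts 548 genes passed (410 higher, 138 lower).

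In BOM cells IFNg raised the same lists: 17 of 17 interferon gamma response genes, 18 of 22 MHC class I genes, 7 of 7 MHC class II genes, 18 of 19 type I interferon genes and 7 of 12 sensors. H2-K1 rose by 5.19 ± 0.15, B2m by 4.58 ± 0.16, Tap1 by 7.94 and Cd274 by 5.60, and the MHC class II gene H2-Eb1, at 0 counts without IFNg, was at least 213-fold higher. The proliferation list fell (median -0.28, adjusted p = 1.01e-09, and adjusted p = 0.0486 with an estimated correlation), with 9 of 22 genes lower when adjusted over the list alone and 2 over all genes. That 2 became 1 without DMSO replicate 2 or 3, BOM replicate 2, DMSO with IFNg replicate 3 or either BOM with IFNg library, and 4 without DMSO replicate 1. The Notch pathway list (median -0.17, adjusted p = 0.00870, and adjusted p = 0.0523 with an estimated correlation) tested lower too. So did the neuroendocrine (-0.14, adjusted p = 0.00891) and fibroblast lists (-0.66, adjusted p = 0.0277), both with adjusted p = 0.265 with an estimated correlation. The neuroendocrine call ended without BOM replicate 2 (0.371) or BOM with IFNg replicate 2 (0.0895), and the fibroblast call without BOM replicate 1 (0.390) or 2 (0.140) or BOM with IFNg replicate 1 (0.416) or 2 (0.0649). edgeR called 314 genes, 264 higher and 50 lower, and 506 without the filter. Leaving out BOM replicate 2, BOM replicate 1 or BOM with IFNg replicate 2 gave 178, 207 and 208 calls.

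With IFNg present, BOM raised all 19 measured type I interferon genes on top of the response to IFNg. The tetherin gene Bst2 rose by 1.84 ± 0.18 (SE, adjusted p = 7.30e-07), from 31.8 to 113 CPM, Xaf1 by 1.66 ± 0.14 and the 2'-5' oligoadenylate synthetase-like gene Oasl2 by 1.54 ± 0.15, from 24.1 to 69.9 CPM. The list's median log2 fold change was 1.54 (adjusted p = 1.39e-10, and adjusted p = 0.00547 with an estimated correlation), and its call held in every alternative run. Cd274 rose by 1.10 ± 0.16 from 29.9 to 63.6 CPM and B2m by 0.59 ± 0.12 from 883 to 1330 CPM, while H2-K1 (1244 against 1137 CPM, 0.13 ± 0.11) and Tap1 (476 against 410 CPM, 0.22 ± 0.08, adjusted p = 0.0750) did not pass. Tap1 passed with limma voom (adjusted p = 0.0237) and with scaling by library size alone (0.0302). For the genes called here both BOM libraries lay above all 3 DMSO libraries.

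Of 12 nucleic acid sensors 7 rose, led by Ddx58 (2.49) and Tlr3 (2.18) (median 0.73, adjusted p = 0.000239, and adjusted p = 0.0965 with an estimated correlation). Of 7 MHC class II genes 5 rose (median 1.05, adjusted p = 0.00323, and adjusted p = 0.146 with an estimated correlation), with Cd74 at 1.73, and 3 rose without either BOM with IFNg library or DMSO with IFNg replicate 2 or 3. Of 22 MHC class I genes 6 rose (median 0.21, adjusted p = 0.0528), 3 without DMSO with IFNg replicate 2 and 2 without BOM with IFNg replicate 2. Of 17 interferon gamma response genes 5 rose and Irf8 fell (-0.58), and adjusted over the list alone 7 rose and 1 fell (median 0.23, adjusted p = 0.122). Irf8 was not called without BOM with IFNg replicate 1, and 3 genes fell without BOM with IFNg replicate 2. Proliferation genes fell, 12 of 22 over all genes and 17 adjusted over the list alone, by small amounts such as -0.50 for Birc5 and -0.37 for Top2a (median -0.30, adjusted p = 4.82e-05, and adjusted p = 0.146 with an estimated correlation). That number was 3 without either BOM with IFNg library and 6 without DMSO with IFNg replicate 3. Of 23 neuroendocrine genes 5 rose and 7 fell (median -0.08, adjusted p = 0.759), and 3 fell without either BOM with IFNg library or DMSO with IFNg replicate 3. The Notch inhibitory ligand gene Dll3 fell by 1.14 on the log2 scale. Of 15 Notch pathway genes 8 rose and 1 fell, and 2 fell without DMSO with IFNg replicate 1 or 3 or BOM with IFNg replicate 1. Of 15 non-neuroendocrine genes 11 rose and 1 fell, with no fall without BOM with IFNg replicate 2, and 6 of 9 fibroblast genes rose, with Notch1 at 3.55 ± 0.13 and Tgfbr2 at 3.31. The adjusted p was 0.0965, 0.146 and 0.146 for these 3 lists with an estimated correlation. Kdm1a fell by 0.40 on the log2 scale (adjusted p = 0.00121). edgeR called 3518 genes, 1979 higher and 1539 lower (960 and 291 at least 2-fold), and 2095 without BOM with IFNg replicate 2. Scaling by library size alone gave 2287 higher and 1072 lower genes.

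Whether the BOM effect differed with IFNg was tested as an interaction. edgeR called 0 genes, with 725 at an unadjusted p under 0.05, limma voom called 0, DESeq2 15 (7 higher, 8 lower) and edgeR without the filter 67 (32 higher, 35 lower). Among lists, the type I interferon response was higher by a median of 0.55 log2 units over 19 members, with 3 passing when adjusted over the list alone (camera adjusted p = 3.71e-14, and adjusted p = 0.00240 with an estimated correlation). Stat2, for example, stood at 37.1 against 41.8 CPM without IFNg and at 265 against 164 CPM with it, an interaction of 0.87. Ifi44 of this list, and H2-Ab1 and H2-DMb1 of the MHC class II list, had 0 counts in both groups without IFNg, so their interactions are not defined, and Ifit3 (5.61), Oas1a (3.48) and Ifit1 (3.33) stood below 1 CPM there. In tests added after seeing the data, without such undefined members, the adjusted p was 2.49e-12 for the type I interferon response (0.00364 with an estimated correlation) and 0.000250 for MHC class II antigen presentation (0.155). Without members at 0 in any group it was 6.82e-11 (0.00503) and 0.0283 (0.147, with 3 of 7 MHC class II genes left). The MHC class II list (adjusted p = 2.47e-06), nucleic acid sensing (median 0.03, adjusted p = 0.00465) and proliferation (-0.20, adjusted p = 4.69e-07) had adjusted p = 0.0903, 0.155 and 0.155 with an estimated correlation. The interferon gamma response had a median of -0.66 (adjusted p = 0.0380, and adjusted p = 0.559 with an estimated correlation), and its direction turned without BOM with IFNg replicate 1 (adjusted p = 0.968). Its call ended without members at 0 in any group (0.0918). Its call also ended without BOM replicate 2 (0.920), DMSO replicate 1 (0.166) or DMSO with IFNg replicate 2 (0.0515) or 3 (0.133), and with scaling by library size alone. The interaction was -1.13 ± 0.36 for Tap1 and 0.20 for Cd274, and neither passed.

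**Figure D3:**
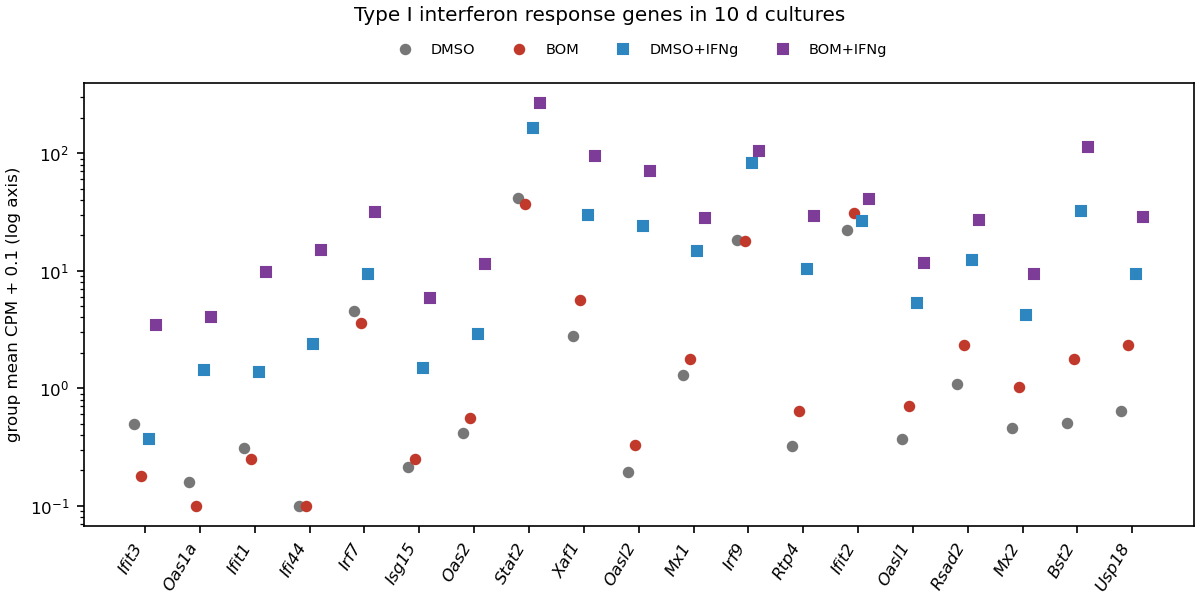
Group mean CPM plus 0.1, on a log axis, of the 19 type I interferon response genes in the 10 d cultures, with circles for groups without IFNg and squares for groups with it. With IFNg every gene lay higher in BOM than in DMSO, as for Oasl2 at 69.9 against 24.1 CPM.

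In flank tumors the question was how BOM, anti-PD1 and both together change the tumor transcripts. BOM alone raised Notch1 from 19.3 ± 22.2 CPM (SD, n = 5) to 89.8 ± 9.60 (n = 4), a log2 fold change of 2.06 ± 0.53 (SE, adjusted p = 0.0160), and the adenylate cyclase gene Adcy5 (ENSMUSG00000022840.9, chromosome 16, 35154877 to 35305738) by 2.06 ± 0.53. Notch1, Adcy5 and the nitric oxide synthase gene Nos1 (1.98) were not called when only these 2 groups were fitted (adjusted p = 0.0696, 0.0703 and 0.0769), nor Nos1 without BOM tumor 2 (0.0586). The contactin gene Cntn4 (ENSMUSG00000064293.14, chromosome 6, 105677660 to 106699310) fell from 29.1 to 0.258 CPM (-6.73 ± 0.60), the retinaldehyde dehydrogenase gene Aldh1a2 (ENSMUSG00000013584.5, chromosome 9, 71215789 to 71296243) from 197 to 5.50 CPM (-5.15 ± 0.45), the serotonin synthesis gene Tph1 from 41.8 to 2.04 CPM (-4.33 ± 0.51) and Hepacam2 from 113 to 5.96 CPM (-4.23 ± 0.51). Cnpy1 (ENSMUSG00000044681.19, chromosome 5, 28200819 to 28245806) had 0 counts in the 4 BOM tumors against 6.41 CPM and was at least 66.1-fold lower. Every BOM tumor lay beyond all 5 vehicle tumors for these genes, which the rule for naming them required. The chloride channel accessory gene Clca3b rose by 1.82 ± 0.42 (98.1 to 358 CPM), whereas it had fallen in the 10 d cultures (-2.86).

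Vehicle tumors 1 and 2 lay between the other vehicle tumors and the BOM tumors for these genes, except that Cnpy1 in vehicle tumor 2 (6.92 CPM) lay within the 5.83 to 8.93 CPM of vehicle tumors 3 to 5. Notch1 stood at 52.5 and 32.2 CPM in them, at 3.01 to 5.21 in vehicle tumors 3 to 5 and at 79.8 to 103 in the BOM tumors, and Aldh1a2 at 68.3 and 114 CPM against 261 to 273 in vehicle tumors 3 to 5. Without vehicle tumors 1 and 2, an alternative added after seeing the data, 3363 genes passed (1689 higher, 1674 lower), and 2020 of them were among the 2082 called with all tumors. The skeletal muscle gene Acta1 stood apart in BOM tumor 2 at 396 CPM, and it reached 24.0 to 55.5 CPM in vehicle tumors 1 and 2 and BOM plus anti-PD1 tumors 3 and 4 and at most 2.83 CPM in the other tumors. The adipocyte gene Adipoq stood at 46.7 CPM in vehicle tumor 4 and 24.6 in BOM tumor 1.

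Neuroendocrine genes fell with BOM in tumors: 13 of 23 fell and 3 rose (adjusted over the list alone 13 and 5), with a median of -0.43 (adjusted p = 0.0195, and adjusted p = 0.997 with an estimated correlation). The call ended without BOM tumor 1 (adjusted p = 0.0595), where 8 genes fell. The neuronal RNA binding gene Elavl4 fell from 138 to 48.1 CPM (adjusted p = 0.00104), the transcription factor gene Neurod1 by 1.52 and the peptide gene Calca by 1.01, while the neuroendocrine regulator gene Insm1 (0.41 ± 0.07) and the peptide gene Grp (1.06) rose. The number that rose was 1 without BOM tumor 4 and 5 without vehicle tumor 2 or BOM plus anti-PD1 tumor 3 or 4. As a mean log2 CPM per tumor, the list's score was 6.30 ± 0.137 in BOM tumors and 6.68 ± 0.119 in vehicle tumors, lower in 4 of 4 (exact two-sided permutation p = 0.00794, the smallest possible here, adjusted p = 0.136 over 120 tests). Of 17 Notch pathway genes 6 rose, among them Rest (1.54) and Notch2, and 2 fell, Dll1 and Jag2 (median 0.34, adjusted p = 0.0881). The 6 became 2 without vehicle tumor 3 or 4 and 3 without vehicle tumor 5, and the 2 became 1 or 0 without vehicle tumor 2, 4 or 5 or BOM tumor 1, 3 or 4. Of 16 non-neuroendocrine genes 3 rose, Snai2 (1.48), Sox9 (1.35) and Zeb1 (median 0.20, adjusted p = 0.0881). This became 0 without vehicle tumor 3, 4 or 5 or BOM tumor 1 or 2 and 1 without BOM tumor 4. As lists, Notch and non-neuroendocrine genes passed without vehicle tumor 1 (adjusted p = 0.0354 and 0.0228), BOM tumor 4 (0.0369 and 0.0336) or vehicle tumors 1 and 2 (0.0168 and 0.0225). Hes1 rose by 0.88 ± 0.24 (adjusted p = 0.0232) and was not called without vehicle tumor 3 (0.0583), 4 (0.0603) or 5 (0.0562) or BOM tumor 4 (0.0542). Kdm1a stood at -0.23 ± 0.07 (adjusted p = 0.0430) and was called only without vehicle tumor 1, anti-PD1 tumor 2 or BOM plus anti-PD1 tumor 3 among the 18 libraries left out in turn (other adjusted p = 0.0515 to 0.139).

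No list of immune genes passed in BOM against vehicle tumors. None of 22 MHC class I genes passed (median -0.06 and mean -0.01, with the test pointing up, adjusted p = 0.991), nor of 7 MHC class II genes (median -0.10, test pointing up), 18 interferon gamma response genes (median 0.10), 18 type I interferon genes (-0.07) or 9 T cell genes (-0.30), each with an adjusted p of 0.991. H2-K1 stood at -0.09 ± 0.25, B2m at -0.09, Tap1 at -0.22 and Cd274 at -0.29. Of 8 cytotoxic lymphocyte genes Gzma fell (-1.86 ± 0.57, 0.589 CPM with BOM, adjusted p = 0.0370). That call ended without vehicle tumor 1 (adjusted p = 0.102) or 4 (0.0563), BOM tumor 1 (0.112), 2 (0.0903) or 4 (0.109), and without vehicle tumors 1 and 2 (0.193). Of 7 T cell checkpoint genes Tox fell (-1.03 ± 0.13) and of 6 dendritic cell genes Zbtb46 rose (0.62 ± 0.13, adjusted p = 0.00535). With any library left out each list still had 1 gene called in that direction, counted without regard to which gene it was. In the 10 d cultures of SCLC cells with IFNg 1 gene of the checkpoint list also fell with BOM. Values of whole tumors therefore do not show in which cells these genes changed. No gene of the macrophage list (17 genes, median -0.01, test pointing up), the fibroblast list (12, 0.24), the B and plasma cell list (4, -0.17), the list of chemokines for T cells (8, -0.03), the adipocyte list (6, -0.69), the erythroid list (5, -0.98, test pointing up) or the skeletal muscle list (10, 2.66) passed.

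For BOM against vehicle edgeR called 2082 of 14332 genes, 845 higher and 1237 lower (111 and 286 at least 2-fold). The count was 1385 when only these 2 groups were fitted (591 higher, 794 lower). It was 1210 without vehicle tumor 5, 1318 without vehicle tumor 4, 1367 without vehicle tumor 3, 1267 without BOM tumor 1 and 1253 without BOM tumor 4. Without the filter on low counts it was 1459. These 2 groups also differed in the number of genes with counts in 1 tumor alone. It was 0 in each BOM tumor and at least 25 in each vehicle tumor, and the cause was not tested.

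**Figure D4:**
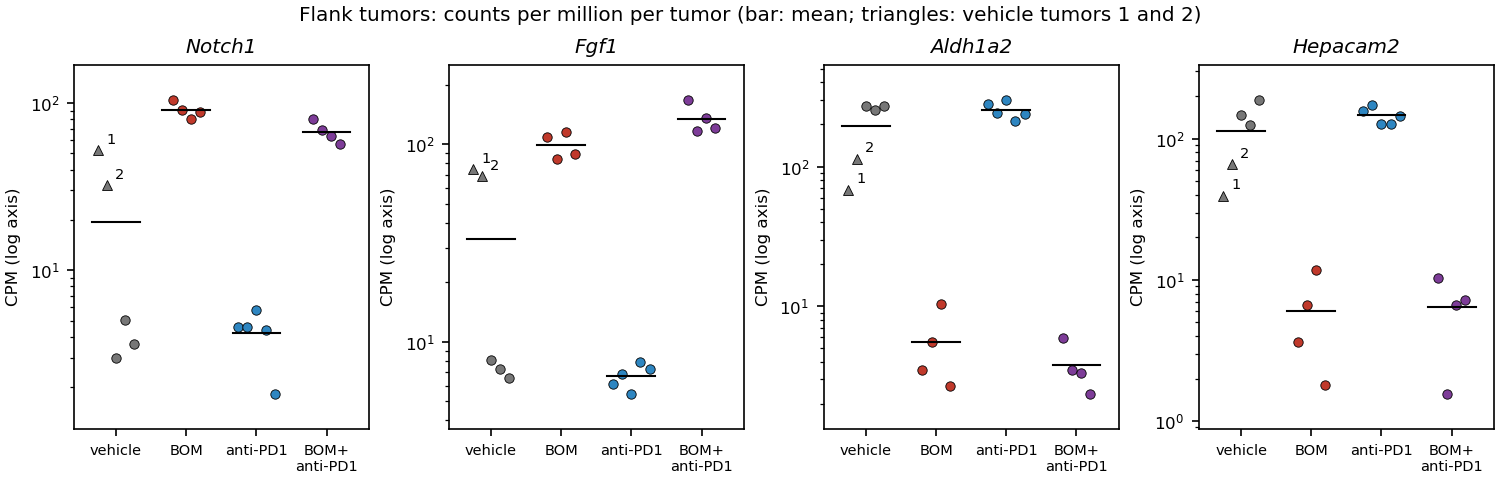
CPM of 4 genes on log axes, with 1 point per tumor, bars at the group mean and triangles for vehicle tumors 1 and 2. Notch1 lay at 79.8 to 103 CPM in the 4 BOM tumors and at 3.01 to 5.21 in vehicle tumors 3 to 5, with vehicle tumors 1 and 2 at 52.5 and 32.2.

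BOM plus anti-PD1 against anti-PD1 alone shares no library with the comparison above. Antigen presentation and interferon genes were higher in the combination: H2-K1 rose from 987 ± 280 CPM (SD, n = 5) to 1840 ± 482 (n = 4), a log2 fold change of 0.90 ± 0.25 (SE, adjusted p = 0.00994), with all 4 tumors above the 5. The class II transactivator gene Ciita rose by 2.15 ± 0.43 (16.0 to 71.1 CPM), the transcription factor gene Irf1 by 1.30 ± 0.22, Tapbp by 1.16 ± 0.25, Erap1 by 1.26 ± 0.22 and the T cell receptor chain gene Cd247 by 1.98 ± 0.53. B2m rose by 0.66 ± 0.21, Tap1 by 1.14 ± 0.36, H2-Aa by 1.84 ± 0.58, Cd274 by 1.27 ± 0.44 (6.84 to 16.5 CPM, adjusted p = 0.0350) and the T cell co-receptor gene Cd8a by 2.23 ± 0.75 (1.01 to 4.82 CPM, adjusted p = 0.0302). Without BOM plus anti-PD1 tumor 1 none of these last 5 passed (adjusted p = 0.0661, 0.0698, 0.0930, 0.132 and 0.0761). Tap1 (0.0606), Cd274 (0.0502) and Cd8a (0.0774) were also not called without BOM plus anti-PD1 tumor 4. Cd274 and Cd8a were not called without anti-PD1 tumor 2 (0.0540 and 0.0535), 3 (0.0513 and 0.0607) or 4 (0.0775 and 0.0684), nor Cd274 without anti-PD1 tumor 5 (0.0667).

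All 18 interferon gamma response genes rose when adjusted over the list alone and 15 over all genes (median 2.09, adjusted p = 1.23e-06, and adjusted p = 0.632 with an estimated correlation), with 9 rising without BOM plus anti-PD1 tumor 1. Of 22 MHC class I genes 17 rose (median 1.10, adjusted p = 9.50e-06, and 0.632 with an estimated correlation), but 6 without BOM plus anti-PD1 tumor 1 and 10 without BOM plus anti-PD1 tumor 4 or anti-PD1 tumor 4. All 7 MHC class II genes rose (median 1.75, adjusted p = 0.00478, and 0.632 with an estimated correlation), but 1 without BOM plus anti-PD1 tumor 1, 3 without anti-PD1 tumor 2 and 2 without anti-PD1 tumor 4 or 5. Of 18 type I interferon genes 9 rose (median 1.10, adjusted p = 0.000249, and 0.632 with an estimated correlation), 15 without anti-PD1 tumor 1, 5 without anti-PD1 tumor 3 and 4 without anti-PD1 tumor 2, 4 or 5 or BOM plus anti-PD1 tumor 1. Of 12 sensors 9 rose, among them Zbp1 (2.19) (median 0.79, adjusted p = 0.000528, and 0.632 with an estimated correlation). As mean log2 CPM per tumor the MHC class I score was 1.01 higher, above the anti-PD1 mean in 4 of 4 tumors (exact two-sided permutation p = 0.0159, adjusted p = 0.190 over 120 tests). The interferon gamma response score was 2.19 higher (exact permutation p = 0.0238, adjusted p = 0.204) and the T cell score 1.18 higher (exact permutation p = 0.0397, adjusted p = 0.260). No score difference passed the adjustment in any comparison.

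Of 9 T cell genes 2 rose, and 1 when adjusted over the list alone (median 1.17, adjusted p = 0.0258, and adjusted p = 0.650 with an estimated correlation). The list's call ended without anti-PD1 tumor 4 (adjusted p = 0.0788) or BOM plus anti-PD1 tumor 1. Only Cd247 still passed when vehicle tumor 2, 3 or 4, BOM tumor 2, anti-PD1 tumor 2, 3, 4 or 5 or BOM plus anti-PD1 tumor 1, 2 or 4 was left out (1 gene). Of 8 cytotoxic lymphocyte genes Cd8a rose (median 1.61, adjusted p = 0.0750), of 7 CD4 and regulatory T cell genes Cd4 (1.82) and of 17 macrophage and monocyte genes Ly6c2 (2.35) (median 0.73, adjusted p = 0.0187, and adjusted p = 0.669 with an estimated correlation). Ly6c2 was not called without BOM plus anti-PD1 tumor 1 (adjusted p = 0.335) or anti-PD1 tumor 2 (0.0536), 4 (0.0655) or 5 (0.0640), and 7 macrophage genes rose without anti-PD1 tumor 1, 3 without vehicle tumor 1 and 2 without BOM tumor 1 or 3. Cytotoxic genes that rose numbered 3 without anti-PD1 tumor 1 or BOM plus anti-PD1 tumor 2, 2 without vehicle tumor 1 or 5 or BOM tumor 2 or 3, and 0 without the libraries named for Cd8a. CD4 and regulatory T cell genes that rose numbered 2 without anti-PD1 tumor 1 or 3. The macrophage list's call ended without BOM plus anti-PD1 tumor 1 (0.0872) and without anti-PD1 tumor 4 or 5. Fibroblast genes (12, median -0.56), endothelial genes (9, -0.22), skeletal muscle genes (10, 6.65), adipocyte genes (6, 1.94) and dendritic cell genes (6, 0.65) did not pass as lists. Of 3 keratinocyte genes Dsp (0.63) and Sfn (0.55) rose (median 0.55, adjusted p = 0.174), and 1 without anti-PD1 tumor 2 or 5 or BOM plus anti-PD1 tumor 2, 3 or 4. Their score was 0.343 higher, in 4 of 4 tumors (exact permutation p = 0.0159, adjusted p = 0.190). For 4 B and plasma cell genes the median was -0.36 and the test pointed up (adjusted p = 0.944).

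The neuroendocrine and Notch changes were present here too. Of 23 neuroendocrine genes 11 fell and 3 rose (median -0.31, adjusted p = 0.00478, and 0.632 with an estimated correlation), with Elavl4 at -1.92 ± 0.24 (181 to 47.9 CPM), Neurod1 at -1.98 and Sez6 at 2.31. Of 17 Notch pathway genes 9 rose, among them Notch1 (4.01), Rest (3.14), Notch2 (2.22) and Hes1 (1.26 ± 0.25, 14.0 to 33.4 CPM), and Dll1 and Jag2 fell (median 0.33, adjusted p = 0.0229, and 0.632 with an estimated correlation). Of Notch genes 1 instead of 2 fell without anti-PD1 tumor 3 or 4 or any BOM plus anti-PD1 tumor. The neuroendocrine score was 0.422 lower and the Notch score 0.807 higher, each in 4 of 4 tumors (exact two-sided permutation p = 0.00794 for both, adjusted p = 0.136). Of 16 non-neuroendocrine genes 3 rose, with Snai2 at 3.26 and Sox9 at 2.77, and 5 without vehicle tumor 1 or 6 without anti-PD1 tumor 1. Of 22 proliferation genes 8 fell (median -0.14, adjusted p = 0.0187, and adjusted p = 0.632 with an estimated correlation), 5 without anti-PD1 tumor 4 or 5 or BOM plus anti-PD1 tumor 3, and without the last the list's call ended (adjusted p = 0.0800). Of 10 LSD1 complex genes 4 fell and 1 rose (median 0.03, mean -0.16, test pointing down, adjusted p = 0.353), and 2 rose without anti-PD1 tumor 2. Kdm1a fell from 573 to 421 CPM (-0.44 ± 0.07, adjusted p = 0.000256). Aldh1a2 fell from 255 to 3.82 CPM (-6.07 ± 0.48), Cntn4 by 5.22 and Cnpy1 by 5.54 on the log2 scale, and Adcy5 rose from 1.32 to 55.1 CPM (5.36 ± 0.75). edgeR called 4637 genes, 2263 higher and 2374 lower (756 and 335 at least 2-fold), and 3727 to 4707 with 1 library left out.

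**Figure D5:**
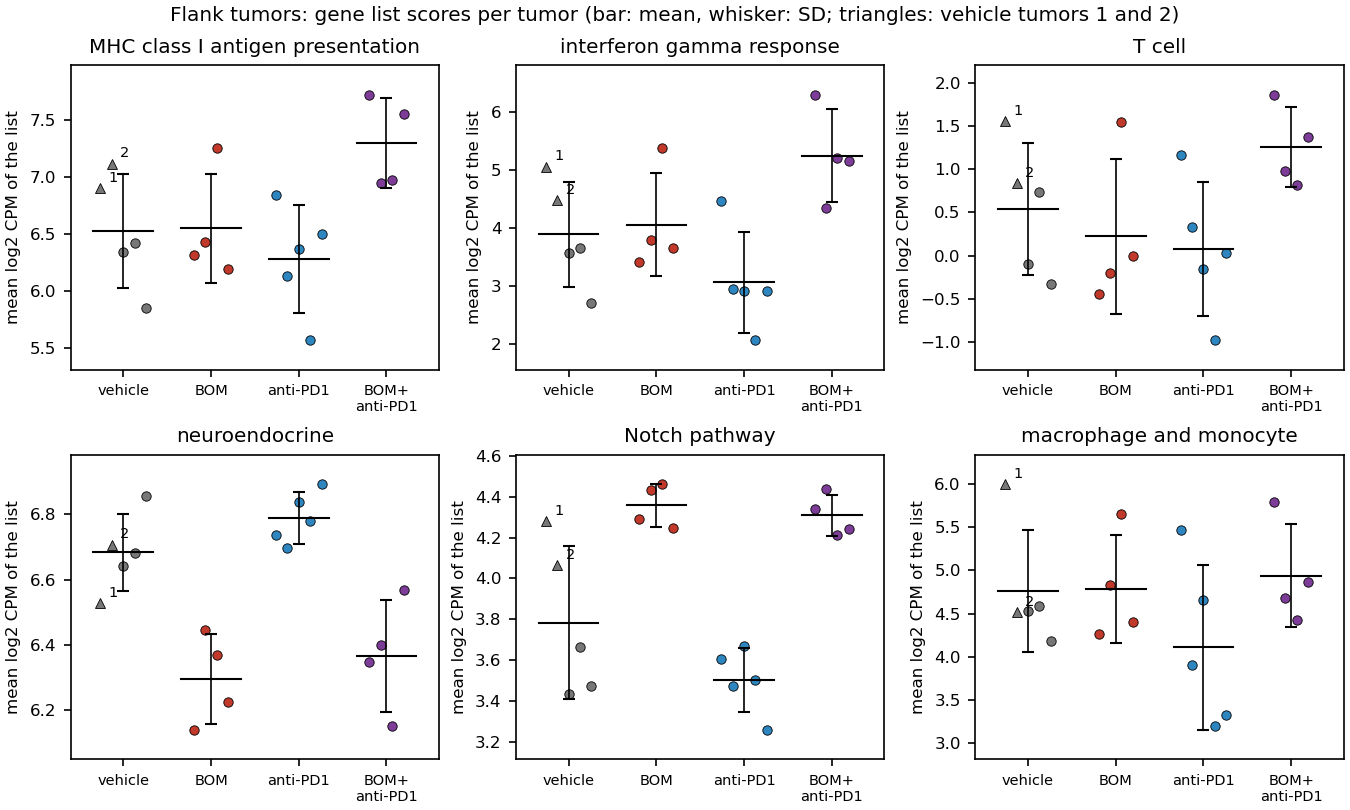
Mean log2 CPM over the genes of 6 lists per tumor, with bars at the group mean, whiskers of 1 SD and triangles for vehicle tumors 1 and 2. The MHC class I score lay at 6.95 to 7.72 in the 4 BOM plus anti-PD1 tumors and at 5.57 to 6.84 in the 5 anti-PD1 tumors, and BOM tumor 3 stood at 7.25 against 6.19 to 6.43 in the other BOM tumors.

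Against vehicle, BOM plus anti-PD1 gave falls of Aldh1a2 (-5.67 ± 0.48, adjusted p = 8.82e-06), Cntn4 (-4.99), Tph1 (-4.47), Hepacam2 (-4.13) and Elavl4 (-1.51), with every tumor of the combination below all 5 vehicle tumors. The growth factor gene Fgf1 rose from 33.1 to 136 CPM (1.92 ± 0.51, adjusted p = 0.0244), Erap1 from 40.0 to 77.4 CPM (0.92 ± 0.22), Irf1 from 72.1 to 130 CPM (0.83 ± 0.22), and all 4 tumors lay above the 5. The naming rule required such a gap between groups of the genes that entered as largest rises or falls. H2-K1 (0.69 ± 0.25, 1840 against 1136 CPM, adjusted p = 0.0779), B2m (0.50), Tap1 (0.87 ± 0.35) and Cd274 (0.76) did not pass. Without vehicle tumors 1 and 2 these 4 passed, with H2-K1 at 1.01 (adjusted p = 0.00723), B2m at 0.68 (0.0394), Tap1 at 1.32 (0.0193) and Cd274 at 1.42 (0.0321), and without vehicle tumor 2 alone H2-K1 (0.0189) and Tap1 (0.0446) passed. Fgf1, Irf1, Hes1 (0.87) and Kdm1a (-0.27) each lost the call without vehicle tumor 3, 4 or 5 or BOM plus anti-PD1 tumor 1 (adjusted p = 0.0501 to 0.0902), Hes1 and Kdm1a also without BOM plus anti-PD1 tumor 3 (0.0912 and 0.105), and Erap1 without BOM plus anti-PD1 tumor 1 (0.0513). With only these 2 groups fitted all 5 lost it (adjusted p = 0.0764 for Irf1, 0.0785 for Erap1 and 0.113 for Fgf1).

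Of 22 MHC class I genes 4 rose and 21 lay above 0 (median 0.79), and of 18 interferon gamma response genes Irf1 rose, 9 when adjusted over the list alone, and all lay above 0 (median 1.29). Both lists had an adjusted p of 6.23e-06, and adjusted p = 0.800 with an estimated correlation. The 4 MHC class I genes became 10 without vehicle tumor 2, 7 without vehicle tumor 1, 2 without BOM plus anti-PD1 tumor 3, 1 without vehicle tumor 3, 4 or 5 or BOM plus anti-PD1 tumor 4 and 0 without BOM plus anti-PD1 tumor 1. The 1 interferon gamma gene became 9 without vehicle tumor 1, 4 without vehicle tumor 2, 2 without BOM tumor 3 or 4, anti-PD1 tumor 1 or BOM plus anti-PD1 tumor 2, and 0 without vehicle tumor 3, 4 or 5 or BOM plus anti-PD1 tumor 1. Nucleic acid sensing had a median of 0.53 (adjusted p = 0.00126), the neuroendocrine list of -0.25 with 8 of 23 genes lower (adjusted p = 0.00807), and MHC class II (0.96), type I interferon (0.46) and Notch (0.19) lists each had an adjusted p of 0.0261. For an estimated correlation the adjusted p was 0.800 for these 5 lists. The MHC class II call ended without vehicle tumor 5 or BOM plus anti-PD1 tumor 4 or 1 (highest adjusted p = 0.138), the type I call without vehicle tumor 2 or BOM plus anti-PD1 tumor 1 (0.368) and the Notch call without BOM plus anti-PD1 tumor 2 (0.0708). T cell (0.54) and cytotoxic (0.76) lists did not pass (adjusted p = 0.0869 each). The cytotoxic list passed without vehicle tumor 1 (0.0266), BOM plus anti-PD1 tumor 2 (0.0152) or vehicle tumors 1 and 2 (0.0114), and the T cell list without BOM plus anti-PD1 tumor 3 (0.0488) or with vehicle tumor 1 thinned (0.0470). The score of 3 keratinocyte genes, of which Dsp rose (0.52), was 0.185 higher, in 4 of 4 tumors (exact two-sided permutation p = 0.00794, adjusted p = 0.136). Non-neuroendocrine genes had a median of -0.04 and a mean of 0.17 with the test pointing up (adjusted p = 0.284). edgeR called 1539 genes, 708 higher and 831 lower (132 and 189 at least 2-fold). The count was 83 (3 higher, 80 lower) when only these 2 groups were fitted and 3284 (1781 higher, 1503 lower) without vehicle tumors 1 and 2, with 1536 of the 1539 genes shared. It was 607, 612 and 650 without vehicle tumor 5, 3 or 4, 797 and 971 without BOM plus anti-PD1 tumor 1 or 2 and 2691 without vehicle tumor 1.

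Anti-PD1 alone gave no called gene against vehicle. H2-K1 stood at -0.20, B2m at -0.16, Tap1 at -0.28, Cd274 at -0.52, Kdm1a at 0.17 and Cd8a at -1.28 ± 0.72 (1.01 against 2.22 CPM, adjusted p = 0.569). As lists, the interferon gamma response (18 genes, median -0.88, adjusted p = 5.16e-05) and the type I interferon response (18 genes, median -0.60, adjusted p = 4.46e-06) lay lower with no member above 0. With an estimated correlation the adjusted p was 0.528 to 0.577 for these lists and for the other 11 that tested lower. MHC class I (-0.26), MHC class II (-0.85), macrophage (-0.60), sensing (-0.17), T cell (-0.51), CD4 and regulatory T cell (-0.63), chemokine (-0.58), Notch (-0.14), non-neuroendocrine (-0.21), skeletal muscle (-6.11) and adipocyte (-3.70) lists also tested lower (adjusted p = 0.000337 to 0.0438). Proliferation (0.08), neuroendocrine (0.12) and LSD1 complex (0.05) lists tested higher (adjusted p = 0.000684, 0.0144 and 0.0434, and 0.528 each with an estimated correlation). Without vehicle tumors 1 and 2 the calls of 13 of these 16 lists ended, all except type I interferon, proliferation and adipocyte, among them the interferon gamma response (0.317), MHC class II (0.583), macrophage (0.102) and MHC class I, whose direction turned (0.835). Type I interferon and proliferation kept their calls under every alternative with a preset correlation, and the adipocyte call ended without vehicle tumor 4 (0.460). Without vehicle tumor 1 alone 13 of these 16 lists lost their calls (all except the interferon gamma response, type I interferon and proliferation), and without anti-PD1 tumor 4 alone 10 did, MHC class I and MHC class II among them. Leaving out any 1 of the other 8 vehicle and anti-PD1 tumors ended 1 to 6 of the calls. edgeR called 0 genes, with 1411 at an unadjusted p under 0.05, limma voom called 0 and DESeq2 83 (23 higher, 60 lower), and with 1 library left out edgeR called 0 to 2.

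Adding anti-PD1 to BOM changed 1 gene past the threshold, Sgsm2, a regulator of RAB GTPases (ENSMUSG00000038351.14, chromosome 11, 74849261 to 74897060), which rose from 30.5 to 44.5 CPM (0.55 ± 0.08, adjusted p = 0.0468). It lost its call under most alternatives, including the one without BOM plus anti-PD1 tumor 2 (adjusted p = 0.451). With 1109 genes at an unadjusted p under 0.05, DESeq2 called 5 genes and limma voom 1. All 22 MHC class I genes (median 0.67, adjusted p = 5.97e-11), all 18 interferon gamma response genes (1.17, adjusted p = 3.35e-09) and all 9 T cell genes (0.98, adjusted p = 2.41e-05) lay higher in the combination, as did 8 of 8 cytotoxic genes (1.55, adjusted p = 6.04e-05). Under an estimated correlation the adjusted p was 0.361, 0.379, 0.361 and 0.367. As mean log2 CPM per tumor these 4 scores were 0.747, 1.19, 1.03 and 1.36 higher. Their exact two-sided permutation p was 0.0857, 0.114, 0.114 and 0.0571, with 0.0286 the smallest possible. BOM tumor 3, at 7.25 for MHC class I and 5.38 for the interferon gamma response, lay within the range of the combination (6.95 to 7.72 and 4.34 to 6.30). MHC class II (1.01, adjusted p = 0.000264) and type I interferon genes (0.64, adjusted p = 2.41e-05) tested higher, and fibroblast (-0.88, adjusted p = 0.000217) and proliferation genes (-0.08, adjusted p = 2.41e-05) lower, with adjusted p = 0.420, 0.483, 0.483 and 0.361 with an estimated correlation. Sensing (0.18) and chemokine lists (0.61) had an adjusted p of 0.0484, and adjusted p = 0.542 with an estimated correlation. Both calls ended without vehicle tumor 3 or 4, BOM tumor 1, 2 or 4, anti-PD1 tumor 2 or 3 or BOM plus anti-PD1 tumor 1 or 3, and the chemokine call without vehicle tumor 2 (0.0503 to 0.357). H2-K1 stood at 0.79 ± 0.26 (adjusted p = 0.557), Tap1 at 1.09 ± 0.38, Cd274 at 1.04 and B2m at 0.59, and none passed.

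Whether BOM changed the tumors more with anti-PD1 than without was tested as an interaction, with 0 genes called by edgeR, 1258 at an unadjusted p under 0.05, 0 by limma voom and 4 by DESeq2. The interferon gamma response had a median interaction of 2.18 (adjusted p = 1.30e-12) with 15 of 18 genes passing when adjusted over the list alone, MHC class I 1.01 (adjusted p = 1.33e-11, 10 of 22), MHC class II 1.86 (adjusted p = 7.24e-06, 6 of 7), type I interferon 1.13 (adjusted p = 8.95e-11, 2 of 18) and T cell 1.47 (adjusted p = 7.24e-06, 1 of 9). For an estimated correlation the adjusted p was 0.228 for these 5 lists. The proliferation list had a median of -0.17 (adjusted p = 1.66e-08, and adjusted p = 0.182 with an estimated correlation). Lists of other cells tested higher as well: cytotoxic lymphocyte (2.24, adjusted p = 0.000443), macrophage (0.76, adjusted p = 0.00154), keratinocyte (3 genes, 0.23, adjusted p = 0.0172), CD4 and regulatory T cell (0.59, adjusted p = 0.0172) and skeletal muscle (3.96, adjusted p = 0.0299). With an estimated correlation their adjusted p was 0.316, 0.578, 0.182, 0.373 and 0.610. The CD4 call ended without vehicle tumor 4 (0.129) or BOM plus anti-PD1 tumor 1 (0.0630), and the muscle call without vehicle tumor 1 or 2, BOM tumor 1, 3 or 4 or BOM plus anti-PD1 tumor 3 or 4 (0.0576 to 0.284) and without vehicle tumors 1 and 2 (0.580). Sensing (0.45, adjusted p = 0.000888) and chemokine lists (1.29, adjusted p = 0.00382) tested higher and the LSD1 complex lower (-0.13, adjusted p = 0.00486), with adjusted p = 0.316, 0.373 and 0.156 with an estimated correlation. H2-K1 stood at 0.99 ± 0.35 (adjusted p = 0.465), Tap1 at 1.37 ± 0.51, Cd274 at 1.56 ± 0.63 and B2m at 0.75.

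Genes called in one comparison were followed in other comparisons that share no library with it, in part in another experiment. BOM without and with IFNg, and BOM without and with anti-PD1, were compared within 1 experiment and 1 fit. Residuals of libraries of the same number without and with IFNg also correlated, by 0.119 to 0.393 for DMSO and 0.200 for BOM. Lists from the same experiment are not independent, so the numbers for independent lists are a low bar for them. Of 1640 genes that rose with BOM at 10 d and were tested at 96 h, 1359 lay above 0 at 96 h, and of 1170 that fell 877 lay below 0 (camera adjusted p = 6.91e-24 and 7.93e-10, and adjusted p = 0.169 and 0.0620 with an estimated correlation). In BOM against vehicle tumors 308 of the genes raised at 10 d were called higher, where 105.8 would be given by independent lists, and 80 lower, where 152.0 would be. Of the genes that fell at 10 d 300 were called lower there against 106.7 for independent lists. Under an estimated correlation the adjusted p of these sets in BOM against vehicle tumors was 0.169 and 0.0620. The genes raised by BOM without IFNg included 1459 raised by BOM with IFNg (238.7 for independent lists) and 1 that fell (adjusted p = 0.000119 with an estimated correlation). Genes raised by BOM in tumors without anti-PD1 included 702 raised by BOM with anti-PD1 (133.4 for independent lists) and none that fell, and 1019 fell in both (204.9 for independent lists), with adjusted p = 0.0436 and 0.00952 with an estimated correlation. Genes raised by IFNg in culture included 159 that rose in BOM plus anti-PD1 against anti-PD1 tumors (43.9 for independent lists) and 11 that fell (48.0), with an adjusted p of 0.179 with an estimated correlation. In BOM against vehicle tumors 20 of them were called higher, against 17.1 for independent lists.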

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

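The tests on labels of whole tumors, genomic DNA and adipose tissue were chosen after results were seen, and the other tests were written down before they were run.

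In tumors 375 library values were tested for lying far from the others of their group, and 37 did, where 18.75 would by chance (about 1 in 20). They were 10 of 104 values of libraries and lists and 27 of 271 values of genes. BOM tumor 3 held 11 of them and vehicle tumor 1 held 10. Vehicle tumor 1 stood apart with 82.2 M counts (nearest other vehicle tumor 13.2 M), scores of 5.59 for non-neuroendocrine (4.68), 6 for macrophage (4.59) and 4.33 for erythroid genes (1.73), and CPM of 159 for Postn, 14.0 for Pdgfra, 878 for Apoe, 25.4 for Itgam, 4.12 for Gzma and 17.6 for Tmem156. BOM tumor 3 stood apart with scores of 4.68 for nucleic acid sensing (4.28) and 1.27 for cytotoxic genes (-0.22), and CPM of 17.1 for Cd274, 7.94 for Lck, 117 for Tapbp, 35.5 for Ms4a7, 348 for H2-Aa, 1.08 for Prf1, 3.36 for Ly6c2, 10.4 for Ccl5 and 2.69 for Zap70. Anti-PD1 tumor 1 did so with 1.93 CPM for Tgtp1, 3.54 for Gzmb, 88.0 for Tapbp and 7.25 for Ccl5.

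Other far values were spread over other tumors. BOM tumor 2 had a skeletal muscle score of 6.87 (nearest other BOM tumor -1.56) and anti-PD1 tumor 2 an adipocyte score of 2.37. BOM plus anti-PD1 tumor 1 had 8.58 CPM of Ly6c2 and 50.3 of Dcn, tumor 2 had 44.1 of H2-M2, and tumor 3 had a B and plasma cell score of 0.71 with 10.0 CPM of Plb1, 4.10 of Tph1 and 50.5 of Spon2. BOM plus anti-PD1 tumor 4 had 18327 genes detected (nearest 18722) and 26.4 CPM of Calca.

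Vehicle tumors 1 and 2 lay between the other vehicle tumors and the BOM-treated tumors in their median position over genes, and depth was excluded as the cause for vehicle tumor 1, since after thinning its score over genes changed by BOM in culture was -0.470 against -1.56 to -1.29 for vehicle tumors 3 to 5 in the same fit. Whole exchanged labels were excluded, since on a scale from anti-PD1 (0) to BOM plus anti-PD1 (1) vehicle tumors 1 and 2 stood at 0.706 and 0.521 (lowest BOM tumor 0.824), and over the 335 falling genes at 0.724 and 0.532 (0.954), although over the rising genes vehicle tumor 1 at 0.683 was close to BOM tumor 2 at 0.693. A mixed sample would fit vehicle tumor 2, where BOM plus anti-PD1 tumor 4 had a weight of 0.532 over genes not used to find the pattern. The reverse weight, of BOM plus anti-PD1 tumor 4 on vehicle tumor 2, was 0.721, so the weights do not say which of the 2 would be mixed. A weight as large also stood between tumors of the same group, with 0.551 for BOM tumor 1 on BOM tumor 4. For vehicle tumor 1 a mixed sample stays open, since the lower of the weights of BOM tumor 3 and BOM plus anti-PD1 tumor 1 was 0.238, and vehicle tumor 4, at 0.0605 on the scale, had a weight of 0.391 on BOM tumor 1. These weights measure likeness, do not show when or how a mixture arose, and do not exclude a biological cause, for which the design holds no test.

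The type I interferon list differed in its response to BOM with and without IFNg, with an adjusted p of 0.00240 with an estimated correlation. With the replicate number as a block and a preset correlation, the camera adjusted p was 2.09e-13. DMSO and BOM groups each held the same numbers with and without IFNg, so an even shift per number cancels in the interaction with or without the block. The block was therefore no test of a batch as the cause. Low starting counts could hide a BOM effect without IFNg: over the 6 members with at least 1 CPM in DMSO the median interaction was 0.518 ± 0.354 (SE), positive in 6 of 6, and this test cannot tell. A joint action of BOM and IFNg on these genes would fit the same values and was not tested apart from them.

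Vehicle tumor 4 had 2630 genes with counts in it alone, where the next tumor had 245. All BOM tumors, anti-PD1 tumors 4 and 5 and BOM plus anti-PD1 tumors 2 to 4 had 0 such genes, and no other tumor had fewer than 25. Why these tumors had none was not tested. All BOM tumors and no vehicle tumor were among them, so between these 2 groups this difference cannot be told apart from BOM treatment. Over all arms it did not follow BOM. Anti-PD1 tumors 4 and 5 had 0 such genes without BOM, and BOM plus anti-PD1 tumor 1 had 48 with it. Genomic DNA in this library would fit: olfactory, vomeronasal and taste receptor genes reached 326 CPM, 8.75 times the highest other tumor (37.3), and 887 of 1397 were detected. Adipose tissue was excluded as the source, since BOM tumor 1 had 0.526 of the Adipoq level of vehicle tumor 4 but 0.0661 of its receptor level.

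Random splits of the libraries tested whether random groups of samples give as many calls. For BOM against vehicle 1 of 100 splits, the real one, reached 2082 calls (highest other 34), for BOM plus anti-PD1 against vehicle 1 of 100 reached 1539 (highest other 1278) and against anti-PD1 1 of 100 reached 4637 (highest other 2661). No other split that was run gave as many calls there. Of 126 possible splits 100 were run, so 1 of 100 was the smallest share possible, and it was not adjusted over comparisons. For anti-PD1 against vehicle (100 of 100 splits), the tumor interaction (100 of 100, highest other 28) and 96 h (10 of 10, highest other 347) the real count was 0, which any split reaches, so these splits say nothing on chance. In anti-PD1 against vehicle a split with vehicle tumors 1 and 2 in the same group called 304 genes, which points to a structure of the samples. For BOM plus anti-PD1 against BOM 3 of 35 reached the real 1 (highest other 1), so chance was not excluded. For IFNg in DMSO (1 of 10 reached 345, highest other 0) the splits were too few for a share under 0.05. With the line as a block, the 347 at 96 h came from splits whose only contrast within a line was BOM against DMSO in G8545.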

How the results depend on the processing

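The fits without vehicle tumors 1 and 2, with vehicle tumor 1 thinned and without Gm26917 and Gm42418, the gene list tests with a library left out, and those of the 10 d interaction without members at 0 counts, were chosen after results were seen. All 173 named results that passed kept their sign in every alternative, and 123 kept their call. Of 118 that did not pass, 28 passed in some alternative. The calls for 10 d BOM (2662 to 3690), BOM with IFNg (3012 to 3715) and BOM plus anti-PD1 against anti-PD1 (3840 to 5075) stayed within 1.5 times of 3094, 3518 and 4637 under other tools, scalings and filters. At 96 h, where 0 genes passed, DESeq2 gave 52, limma voom 3, library size alone 2 and no filter 310, and leaving out a line gave 0 to 149. The 10 d interaction (0) became 15 with DESeq2 and 67 without the filter, and 0 to 1 with a library left out. Without the filter IFNg in DMSO gave 548 (345) and IFNg in BOM 506 (314). With a library left out 10 d BOM ranged from 1858 to 3230, BOM with IFNg from 2095 to 3729 and IFNg in BOM from 178 to 356. In tumors BOM against vehicle gave 1385 with only these groups fitted and 3363 without vehicle tumors 1 and 2, and 1210 to 2971 with a library left out. BOM plus anti-PD1 against vehicle gave 83, 3284 and 607 to 2691 in the same order. Anti-PD1 against vehicle gave 83 with DESeq2 and 0 to 2 with a library left out, and the tumor interaction gave 4 with DESeq2. The 1 call of BOM plus anti-PD1 against BOM became 5 with DESeq2 and 0 with a 1 CPM filter, no filter, RLE, only these groups fitted, vehicle tumor 1 thinned or vehicle tumors 1 and 2 left out, and was 0 to 1 with a library left out. Of 247 gene list tests 95 passed, and 13 with an estimated correlation, and 0 of 120 tumor list scores passed under any setting. Fitting only the groups compared uses fewer samples and takes the spread from these groups alone. Both comparisons with vehicle held 4 and 5 tumors there, yet gave 1385 (2082) and 83 (1539) calls. Vehicle tumors could differ more among themselves than anti-PD1 tumors, for example in Notch1 (3.01 to 52.5 against 1.83 to 5.89 CPM). A spread shared by all arms may therefore be too small for vehicle comparisons. The cause of these and the other changes was not tested.

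Among list results called in the main fit or in the alternative, only 2 turned direction. Lists called in neither were not counted. The interferon gamma response in the 10 d interaction went from an adjusted p of 0.0380 to 0.968 without BOM with IFNg replicate 1, and was 0.000213 without BOM with IFNg replicate 2. The MHC class I list in anti-PD1 against vehicle went from 0.0113 to 0.835 without vehicle tumors 1 and 2. For both the cause was not tested.

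With the replicate number as a block, the 10 d interaction gave 10 calls, IFNg in DMSO 478 and BOM plus anti-PD1 against BOM 0. For IFNg in DMSO, where libraries of the same number correlated by 0.119 to 0.393, the block gave a call to Chga, Cd44 and the fibroblast list and changed no other call of a named gene or list. The block ended the call of the interferon gamma response in the 10 d interaction (adjusted p = 0.0903) and gave a call to nucleic acid sensing (0.0392) and type I interferon (0.0359) for 10 d BOM, whose groups share only 2 numbers. Tumors of the same number did not pair, with correlations between vehicle and anti-PD1 tumors from -0.156 to 0.512. With the block BOM against vehicle gave 1617 calls, BOM plus anti-PD1 against vehicle 1111 and against anti-PD1 3936, the fibroblast list passed in BOM plus anti-PD1 against vehicle (0.0401), and the skeletal muscle call of the tumor interaction ended (0.0586). The 10 d pairs that share 2 numbers gave 3383 calls for BOM, 3777 for BOM with IFNg and 458 for IFNg in BOM. Without the line as a block at 96 h 0 genes passed.

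Depth limits genes of low counts: Tap1 at 0.725 CPM in DMSO cells and T cell genes of a few CPM in tumors rest on few counts. Leaving out a BOM library of the 10 d cultures left 1 library in that group, whose spread was then taken from the other groups.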

Other observations

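No test in this part was chosen to explain a result, and the genes were picked after their values were seen.

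In all tumors the oncogene Mycl stood at 8413 to 12287 CPM. The sensors Tlr3 and Ddx58 rose with BOM in culture both without IFNg (2.35 and 1.49) and with it (2.18 and 2.49). The glycosyltransferase gene Mgat4c fell in culture without and with IFNg (-4.30 and -5.65). Among chemokines for T cells, Cxcl10 (2.06) and Cxcl16 rose in BOM plus anti-PD1 against anti-PD1 tumors (median of 8 genes 0.97, adjusted p = 0.0692), and the number that rose was 1 without BOM plus anti-PD1 tumor 1 and 4 without vehicle tumor 1, BOM tumor 3, anti-PD1 tumor 1 or BOM plus anti-PD1 tumor 2. Of 7 T cell checkpoint genes Havcr2 (1.69) and Entpd1 (1.17) rose and Tox (-1.16) fell there (adjusted p = 0.425), with 1 rise without anti-PD1 tumor 4 or 5 and 0 without BOM plus anti-PD1 tumor 1.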
